A study of Homo sapiens with 4 samples.

How the data were processed

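Total RNA from HeyA8-MDR cells was hybridised to Affymetrix Human Clariom S arrays, 1-colour arrays that summarise several short probes into 1 value per feature. Per the labels, there were 4 arrays: 2 of cells without a miR-204 label and 2 of cells labelled miR204. The treatment note names the miR-204-5p inhibitor for all 4, so the control group was assigned from the sample titles together with the design text, which describes cells given a control inhibitor or the miR-204-5p inhibitor. The deposited values were log2 expression values made with RMA, a method that corrects background, quantile-normalizes arrays and summarises probes, in Transcriptome Analysis Console 4.0, per the submitters' processing notes. Parameters of that step and the genome build were not given in the sources used here, and no coordinates are reported. The values ran from 1.61 to 13.1 with similar but not equal distributions between arrays, with standard deviations of 2.20 and 2.21 in the controls and 2.08 and 2.13 in the inhibitor arrays. Signal over background and detection calls were not analysed here, so a dim feature could not be told from an undetected one.

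The table held 21448 features, and 0 control features had to be left out. Gene symbols came from the platform annotation: 17709 features had 1 symbol, with 17687 distinct symbols, 0 had several and 3739 had none and stayed unnamed. Where several features shared a symbol, the feature with the highest mean over the 4 arrays stood for the gene. No values were floored or filtered in the main fit.

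Groups were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit and eBayes and without a replicate block. The moderated test had 2 residual and 4.78 prior degrees of freedom, p-values were adjusted by the Benjamini-Hochberg method over all features, and the threshold was an adjusted p of 0.05. A second, descriptive set used at least 2-fold with an unadjusted p under 0.05. A permutation of the group labels of 2 against 2 arrays cannot give an exact p below 0.333, so no single value was tested that way. Intervals of log2 differences are at the 95% level from the moderated test.

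In total 32 gene lists with 869 genes, of which 780 were measured, were fixed before the data were examined, along with the design, the other settings to be tried and the rule for naming genes. The lists covered reported miR-204 targets, angiogenesis promoters and inhibitors, drug efflux and taxane resistance, S phase, mitosis, core and linker histones, p53, interferon, NF-kappaB, hypoxia, the unfolded protein, amino acid, heat shock, NRF2 and immediate early responses, cholesterol synthesis, mesenchymal and epithelial genes, TGF-beta, YAP and Notch, apoptosis, autophagy, glycolysis, oxidative phosphorylation, ribosomal proteins, the microRNA machinery, ovarian carcinoma genes and markers of endothelial cells, leukocytes and fibroblasts. Some genes sit in several lists. Each list was tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it had little power to call a list. Members were also counted with the adjustment made over the list alone. List medians were compared with those of 10000 random lists of the same size matched on expression level in 50 bins. Named genes were up to 15 features in each direction with the largest change among those past the threshold without overlap between groups and with 1 symbol, up to 4 members per list with the largest moderated statistic, and THBS1, ABCB1, TRPM3, BCL2, SIRT1, FOXC1, TGFBR2 and VEGFA in any case.

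The procedure was tested on simulated data with 200 changed features in each of 5 simulations per fold size. Means were those of the real features, spreads were drawn from the variance prior of the fit, and features varied independently. At 2-fold, 0% of the changed features were recovered, and at 4-fold 96.6% were, with 4.36% of calls false. A list shifted by 0.5 log2 units was called in 10 of 10 simulations, and 1 of 310 unchanged lists was called. Without correlation between members or a trend with expression level, the simulation cannot show how often camera calls unchanged lists in the real data.

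Other settings chosen beforehand were an intensity trend or a robust prior in eBayes, the replicate number as a block, quantile normalization of the deposited values again, equal array medians, leaving out features below the 25th percentile or the median of mean expression, leaving out each array in turn, an ordinary test without moderation, limma's treat with a minimum of 1.2-fold, and the other list tests. When 1 array was left out, the lone array of its group was assumed to vary like the other group. Such a fit had fewer residual degrees of freedom, and 2.79 or 2.33 prior degrees of freedom against 4.78. It can therefore lose calls where the difference is no smaller. Counts lost in these fits do not show that a change rests on the left-out array. Cyclic loess, quantile normalization together with the trend, and array weights were added after the data were seen. A planned test of miR-204-5p seed matches in 3' untranslated regions was not run, because transcript sequences were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.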

Results

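Gene expression was measured in HeyA8-MDR cells, a multidrug-resistant human ovarian carcinoma line that was kept in medium with 15% serum and 300 ng/ml paclitaxel. The cells had received either a control microRNA inhibitor or an inhibitor of miR-204-5p. Such an inhibitor is an antisense oligonucleotide that binds a mature microRNA and blocks it. Each group had 2 arrays, and each array gave a log2 expression value for 21448 features, of which 17709 carried 1 gene symbol and 3739 were unnamed here. The arrays with a miR-204 label were taken as the inhibitor group and the others as the control group, because the treatment note reads the same for all 4 arrays and the design text names the control. Array medians were 5.65 and 5.68 log2 units in the controls and 5.59 and 5.61 in the inhibitor arrays. Pearson correlations across features were 0.995 between the controls, 0.986 between the inhibitor arrays and 0.984 to 0.989 between groups. The number of arrays limits the precision, and nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The level of miR-204-5p itself was not analysed here, so its loss was not checked.

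The comparison asked which transcripts differ once miR-204-5p is blocked, in a study of microRNAs linked to angiogenesis. The largest increase past the threshold was that of IL6, a pro-inflammatory cytokine, which rose from 4.04 ± 0.29 to 6.97 ± 0.134 log2 units (SD, n = 2 per group), 7.62-fold with a log2 standard error of 0.185 (adjusted p = 0.028). Its control values of 4.24 and 3.83 lay near the dimmest 25% of features (up to 3.965), and signal over background was not analysed here, so this fold is uncertain and may be a lower bound. EGR1, an immediate early transcription factor, rose 4.56-fold (log2 change 2.19, SE 0.185, adjusted p = 0.039). DDIT3, the stress-induced transcription factor also called CHOP, rose 4.26-fold (log2 change 2.09, SE 0.171, adjusted p = 0.039). CXCL8, the chemokine interleukin-8, rose from 8.05 ± 0.0212 to 9.55 ± 0.0707 (SD, n = 2 per group), which is 2.84-fold (adjusted p = 0.041). IL7R, the receptor chain for interleukin-7, rose 3.43-fold, and CREBRF, a regulator of the stress factor CREB3, rose 3.10-fold. TM4SF19, which encodes a tetraspanin-like membrane protein, rose 4.24-fold, and the read-through transcript TM4SF19-DYNLT2B rose 4.71-fold. The latter pair overlaps in the genome and was not resolved from each other. HSPA1A, an inducible heat shock protein with a near-identical gene copy that the probes may not separate, rose 2.78-fold.

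Those 9 genes and 2 unnamed features, TC0600007616.hg.1 at 2.87-fold and TC1800009242.hg.1 at 3.49-fold, made up the 11 features past an adjusted p of 0.05 in limma, all higher with the inhibitor and 0 lower. TC0600007616.hg.1 had values of 7.44 and 7.23 in the controls and 8.86 and 8.85 with the inhibitor. They lay close to those of HSPA1A (7.36 and 7.28, then 8.79 and 8.80). With the overlapping TM4SF19 pair, the 11 features need not be 11 separate changes. At an unadjusted p under 0.05, 3831 features differed, 1096 higher and 2735 lower, against 1409 higher and 1523 lower after quantile normalization. A change of at least 2-fold with an unadjusted p under 0.05 was found for 108 features, 64 higher and 44 lower. The split was 85 higher and 27 lower with equal array medians, and 76 higher and 29 lower after quantile normalization. No value of the control arrays overlapped those of the inhibitor arrays for 50.3% of features, against 33.3% by chance. The count of 11 moved with the settings: it was 1525 with an intensity trend in limma's prior (219 higher, 1306 lower), 559 with that trend after quantile normalization (304 higher, 255 lower), 1011 (144 higher, 867 lower) over features above the median level, and 0 after quantile normalization. It was also 0 without control array 1, control array 2, inhibitor array 1 or inhibitor array 2, with lowest adjusted p of 0.713, 0.834, 0.243 and 0.139, while all 11 features stayed higher in each of these fits.

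**Figure D1:**
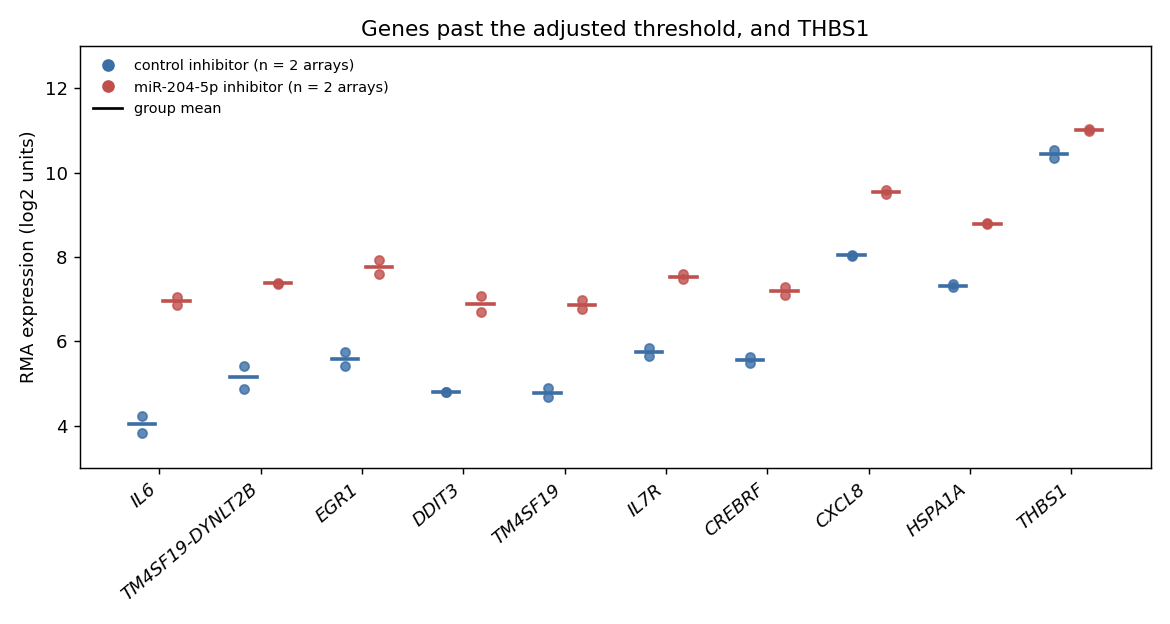
Log2 expression of the 9 named genes past the adjusted threshold and of THBS1, with 1 point per array (2 control inhibitor, 2 miR-204-5p inhibitor) and lines at group means. For each gene both inhibitor arrays lie above both control arrays, from 4.04 to 6.97 for the means of IL6 and from 10.44 to 11.02 for those of THBS1.

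THBS1 encodes the matrix glycoprotein and angiogenesis inhibitor thrombospondin-1 and was named beforehand as a reported miR-204-5p target. Its values were 10.44 ± 0.127 in the controls and 11.02 ± 0.0354 with the inhibitor (SD, n = 2 per group). The log2 difference was 0.57 (SE 0.147, 95% interval 0.224 to 0.926), or 1.49-fold, and it did not pass the threshold over all features (adjusted p = 0.17) or adjusted over the list of reported targets alone (0.075). Both inhibitor arrays lay above both controls. It passed with the intensity trend (adjusted p = 0.0038), over features above the median level (0.036) and with quantile normalization and trend together (4.1e-04). Its adjusted p ranged from 4.1e-04 to 0.32 over the settings that kept all 4 arrays. That list held 36 measured messenger RNAs reported as targets of miR-204-5p or its seed sibling miR-211-5p. Adjusted over the list alone, 1 rose (CXCL8, also past the threshold over all features) and 1 fell (ELOVL6, a fatty acid elongase, log2 change -0.85, SE 0.177), and 34 did not pass. That count was 4 risen and 1 fallen after quantile normalization and after cyclic loess, 4 and 2 with the intensity trend, 0 and 0 without control array 1 or control array 2, and 1 and 0 without inhibitor array 1. The list median was -0.11, or 0.01 after quantile normalization and 0.04 after cyclic loess, and camera gave an adjusted p of 0.90. Other reported targets differed by less: the survival factor BCL2 by -0.08 (SE 0.151, adjusted p = 0.81; 0.02 after quantile normalization), the deacetylase SIRT1 by 0.12 (SE 0.154, 0.71), the TGF-beta receptor TGFBR2 by -0.47 (SE 0.166, 0.23) and the transcription factor SNAI2 by 0.44 (SE 0.144, 0.21). TRPM3, the host gene of miR-204, differed by 0.38 (SE 0.15, adjusted p = 0.26), and FOXC1 had no named feature here.

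Genes of cell proliferation had lower values in the inhibitor arrays. All 34 measured genes of S phase and DNA replication were lower, with a median log2 change of -0.59, and 31 of them fell adjusted over the list alone while 0 passed over all features. Examples were the replication factors GINS1 (-0.92, SE 0.149), MCM3 (-0.74, SE 0.14) and GINS2 (-0.80, SE 0.153) and the transcription factor E2F1 (-0.94, SE 0.175). All 35 genes of G2 and mitosis were lower (median -0.55), and 29 fell adjusted over the list alone and 0 over all features. Among them were the kinetochore genes CENPF (-0.72, SE 0.145) and NUF2 (-0.67, SE 0.143), the checkpoint gene MAD2L1 (-0.71, SE 0.145) and the spindle motor KIF11 (-0.66, SE 0.14). Of 37 replication-dependent histone genes, core and linker histones together, 35 were lower (median -0.50), and 26 fell adjusted over the list alone and 0 over all features, such as the core histone H2BC14 (-1.25, SE 0.139, adjusted p = 0.072) and the linker histone H1-3 (-0.97, SE 0.145, adjusted p = 0.12). Histone genes have close copies, so single members are uncertain. Camera with its preset correlation gave adjusted p-values of 5.4e-15 for S phase, 2.7e-14 for mitosis and 2.4e-12 for histones. With an estimated correlation camera did not call them, at adjusted p = 0.44 for S phase, adjusted p = 0.44 for mitosis and adjusted p = 0.35 for histones. That variant rests on 2 residual degrees of freedom and had little power. The list medians stayed below 0 under all settings. The counts of fallen members became 17 for S phase, 0 for mitosis and 7 for histones after quantile normalization. Without control array 1 the S phase, mitosis and histone medians were -0.608, -0.59 and -0.495. Without control array 2 they were -0.575, -0.495 and -0.525.

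Cytokine genes controlled by NF-kappaB had higher values. Of 25 measured members, 20 were higher (median log2 change 0.29), and 7 rose adjusted over the list alone, of which 2, IL6 and CXCL8, passed over all features. TNFAIP3, a feedback inhibitor of NF-kappaB, rose on the list alone by 1.02 (SE 0.152) and the signalling adaptor TRAF1 by 0.72 (SE 0.154). The camera adjusted p was 2.3e-08, and adjusted p = 0.35 with an estimated correlation. Of 28 immediate early genes, which respond within minutes to growth factors or handling, 2 rose adjusted over the list alone, EGR1 and ATF3, a stress-induced transcription factor (1.47, SE 0.171), and EGR1 alone passed over all features. JUND had a difference of 0.56 (SE 0.146) and FOSB one of -0.60 (SE 0.172), and neither passed. The immediate early list had a median of 0.14 and a camera adjusted p of 0.0068, with adjusted p = 0.57 with an estimated correlation. After quantile normalization 12 NF-kappaB genes and 9 immediate early genes rose and 1 of the latter fell. With the intensity trend 7 immediate early genes rose and 3 fell. Without control array 1, control array 2, inhibitor array 1 or inhibitor array 2 the NF-kappaB count was 2, 2, 3 and 4. The immediate early count was 1 without control array 1, and that list's call was lost without inhibitor array 2 (adjusted p = 0.071, range over settings 1.1e-07 to 0.071), with a median of 0.05.

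Camera with its preset correlation also called 5 lists of stress, cholesterol and p53 genes higher. With an estimated correlation it called none of the 5 (adjusted p = 0.44 to adjusted p = 0.64). The heat shock list was not called, with 9 genes higher and 9 lower. In the unfolded protein response, the reaction to misfolded protein in the endoplasmic reticulum, 5 of 26 genes rose adjusted over the list alone and 1, DDIT3, over all features. HERPUD1, a factor of endoplasmic reticulum protein degradation, differed by 1.19 (SE 0.144) and the chaperone HSPA5 by 0.79 (SE 0.149). Of 28 amino acid response genes induced through ATF4, 6 rose adjusted over the list alone and 0 over all features, including the cystine transporter SLC7A11 (1.495, SE 0.161, adjusted p = 0.069), its partner SLC3A2 (0.88, SE 0.142), ATF3 and the pseudokinase TRIB3 (0.76, SE 0.142). Of 21 NRF2 targets, the genes of the oxidative stress response, 5 rose adjusted over the list alone and 0 over all features, including the quinone reductase NQO1 (1.23, SE 0.14), heme oxygenase HMOX1 (1.06, SE 0.139) and the aldo-keto reductase AKR1C1 (1.15, SE 0.17), which has close paralogs. Of 20 cholesterol synthesis genes, 16 were higher and 3 rose adjusted over the list alone and 0 over all features: MSMO1 (0.72, SE 0.149), HMGCS1 (0.69, SE 0.151) and HSD17B7 (0.58, SE 0.143). Of 25 p53 targets, 2 rose adjusted over the list alone and 0 over all features, TP53INP1 (1.12, SE 0.143) and GADD45A (0.80, SE 0.138), while the p53 inhibitor MDM2 (0.47, SE 0.145) did not pass. The heat shock list did not pass as a whole (median 0.02, adjusted p = 0.069) but did after quantile normalization (0.0011, range over settings 1.6e-05 to 0.53). In it 3 of 18 genes rose adjusted over the list alone and 1 over all features: HSPA1A and the co-chaperones DNAJB1 (1.02, SE 0.192) and DNAJB4 (0.80, SE 0.18).

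Median log2 changes of these lists were 0.12 for the unfolded protein response, 0.08 for the amino acid response, 0.18 for NRF2 targets, 0.17 for cholesterol synthesis and 0.07 for p53 targets. Camera gave adjusted p-values of 2.4e-04, 0.0037, 0.0018, 1.3e-04 and 0.003 in that order. None of the 5 was called when the correlation was estimated, a variant with little power here: adjusted p = 0.64 for the unfolded protein response, adjusted p = 0.64 for the amino acid response, adjusted p = 0.44 for NRF2 targets, adjusted p = 0.57 for cholesterol synthesis and adjusted p = 0.57 for p53 targets with an estimated correlation. The estimates in that order were 0.27, 0.18, -0.01, 0.2 and 0.045. Where they exceed the preset 0.01, the preset p-values may be too small. Without inhibitor array 2 the calls of the amino acid response (adjusted p = 0.14, range over settings 3.5e-07 to 0.14), NRF2 targets (0.082, range 3.8e-07 to 0.082) and p53 targets (0.082, range 2.2e-09 to 0.082) ended. Their medians in that fit were 0.02, 0.045 and 0.06, so the p53 median hardly moved. Over features above the median level the NRF2 median was -0.02. The number of risen members ranged over the settings from 1 to 15 for the unfolded protein response, 0 to 15 for the amino acid response, 3 to 8 for NRF2 targets, 0 to 11 for cholesterol synthesis, 0 to 9 for p53 targets and 1 to 7 for heat shock. The number of fallen members ranged from 0 to 6 for the amino acid response, 0 to 4 for heat shock and 0 to 1 for the unfolded protein response and NRF2 targets, and was 0 for cholesterol synthesis and p53 targets. With the intensity trend 11 amino acid response genes rose and 6 fell, and 4 heat shock genes rose and 4 fell. Without control array 1 and without control array 2 it was 1 and 1 for the unfolded protein response, 0 and 2 for the amino acid response, 3 and 3 for NRF2 targets, 0 and 0 for p53 targets and 1 and 1 for heat shock. The cholesterol synthesis median was 0.122 without control array 1 and 0.222 without control array 2. It was 0.295 without inhibitor array 1 and 0.052 without inhibitor array 2. Fits with 1 array left out have fewer degrees of freedom, so fewer members can pass in them.

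Secreted and surface factors that promote vessel growth went both ways. Of 38 measured angiogenesis promoters, 16 were higher and 22 lower, and 7 rose and 2 fell adjusted over the list alone, against 8 and 0 after quantile normalization and 9 and 0 after cyclic loess, and 2, IL6 and CXCL8, rose over all features. ADM, the vasodilator adrenomedullin, rose on the list alone by 0.66 (SE 0.148) and NRP2, a co-receptor of vascular growth factors, fell on it by 0.66 on the log2 scale (SE 0.141). VEGFA, the main vascular endothelial growth factor, differed by 0.41 (SE 0.145, adjusted p = 0.22) and did not pass. The list's median was -0.055, its mean was 0.134 and camera's direction was up, with an adjusted p of 0.057. Of 30 angiogenesis inhibitors, 1 fell adjusted over the list alone and 0 over all features, SPRY1, an inhibitor of growth factor signalling (-0.98, SE 0.179). SERPINF1 differed by -0.49 (SE 0.142) and COL4A1 by -0.51 (SE 0.151), and the list did not pass (median -0.05, adjusted p = 0.90). The inhibitor means of SPRY1 (3.775) and SERPINF1 (3.77) lay within the dimmest 25% of features (up to 3.965), so both differences are uncertain. Of 28 hypoxia response genes, 4 rose and 1 fell adjusted over the list alone and 0 over all features, with ADM, the glucose transporter SLC2A3 (0.66, SE 0.167) and DDIT4 (0.69, SE 0.176) higher and the glycolytic regulator PFKFB3 (-0.54, SE 0.141) lower, and the list did not pass (median -0.06, adjusted p = 0.15). The hypoxia count was 8 risen and 1 fallen after quantile normalization, equal array medians or cyclic loess, and 8 and 3 with the intensity trend. After quantile normalization the promoter and hypoxia lists passed (adjusted p = 0.0033, range over settings 6.9e-04 to 0.55, and 0.034, range 0.0024 to 0.45) with medians of 0.05 and 0.10. In the promoter list 2 genes rose and 0 fell when any of the 4 arrays was left out, and in the hypoxia list 0 rose without control array 1, control array 2 or inhibitor array 1 and 2 rose and 2 fell without inhibitor array 2.

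Highly expressed housekeeping genes had lower values too. Of 37 genes of oxidative phosphorylation, the mitochondrial respiratory chain, 35 were lower (median -0.24) and 0 passed, adjusted over the list alone or over all features. With the intensity trend 15 of them fell adjusted over the list alone, as did 9 ribosomal and 3 glycolysis genes, and without inhibitor array 2 1 gene of oxidative phosphorylation fell. ATP5F1A differed by -0.48 (SE 0.14) and UQCRQ by -0.47 (SE 0.146). Of 27 ribosomal protein genes 26 were lower (median -0.17, but 0.03 after cyclic loess) and 0 passed. RPS14 differed by -0.47 (SE 0.14) and RPL19 by -0.28 (SE 0.14), and such genes share sequence with pseudogenes. Camera called both lists (adjusted p = 4.6e-04 and 0.03), and they had adjusted p = 0.64 and adjusted p = 0.69 with an estimated correlation. Of 18 glycolysis genes 17 were lower (median -0.19) and 0 passed, and the list did not pass (adjusted p = 0.069), but it did with the intensity trend (0.0051, range over settings 0.0051 to 0.97). PKM differed by -0.25 (SE 0.139) and LDHB by -0.31 (SE 0.145). The change depended on the expression level over all features: the median log2 change was 0.07 in the dimmest 25% of features and -0.20 in the brightest 25%, where 81.2% of features were lower. After quantile normalization the oxidative phosphorylation and ribosomal calls ended (adjusted p = 0.35, range over settings 2.1e-06 to 0.40, and 0.51, range 7.6e-05 to 0.72), with medians of -0.05 and -0.03. The ribosomal call also ended without features below the 25th percentile (camera adjusted p = 0.11) or the median (0.37) and with cyclic loess (0.72). It ended too without control array 1 or inhibitor array 1, where the medians were -0.20 and -0.135.

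**Figure D2:**
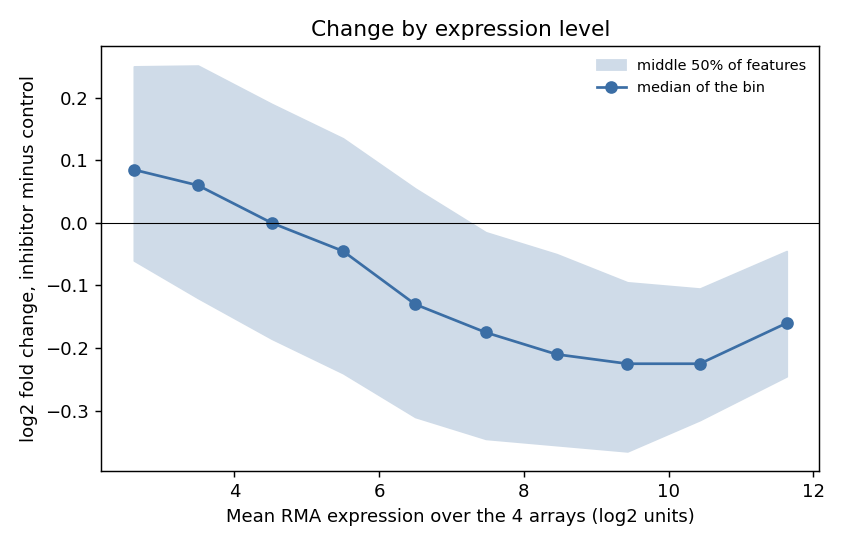
Median log2 fold change (inhibitor minus control) of features in 10 bins of mean RMA log2 expression over the 4 arrays, with the middle 50% of features shaded. The median was 0.09 in the dimmest bin and -0.23 in the bins near 9.43 and 10.43 log2 units.

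Genes linked to drug resistance and to cell identity passed in few cases. Of 23 efflux pump and tubulin genes 0 passed. ABCB1, the multidrug efflux pump P-glycoprotein, differed by -0.11 (SE 0.144, adjusted p = 0.71; 0.06 after quantile normalization), ABCC4 by -0.56 (SE 0.144) and ABCG2 by 0.66 (SE 0.204). The list had a median of -0.18 and an adjusted p of 0.24. With the intensity trend 6 of its genes fell adjusted over the list alone and the list was called lower (adjusted p = 0.042, range over settings 0.042 to 0.80). Among 38 interferon response genes 0 passed, 19 were higher and 19 lower (median -0.002, adjusted p = 0.15), with IFIT2 at 0.92 (SE 0.253) and SAMD9 at -0.60 (SE 0.145). That list was called higher without features below the median level (adjusted p = 0.043, range over settings 0.043 to 0.53). In 26 apoptosis regulators 1 fell adjusted over the list alone, BCL2A1, a survival factor of the BCL2 family (-1.20, SE 0.156; list adjusted p = 0.51). SQSTM1, an autophagy receptor that is also an NRF2 target, rose alone of 28 autophagy and lysosome genes on that list (1.08, SE 0.141), and that list had an adjusted p of 0.26, or 0.0011 after quantile normalization (range over settings 2.4e-05 to 0.75). Of 19 Notch signalling genes 2 rose adjusted over the list alone, JAG1 (0.57, SE 0.14) and HEY1 (0.56, SE 0.157), and 2 fell, RBPJ (-0.80, SE 0.162) and MAML2 (-0.80, SE 0.174; list adjusted p = 0.10). ANKRD1 rose alone of 20 YAP targets (1.16, SE 0.217, list adjusted p = 0.42). Its control values of 3.31 and 3.81 and all values of ABCG2 (2.59 to 3.52) lay within the dimmest 25% of features (up to 3.965). Both changes are therefore uncertain. Among 19 ovarian carcinoma genes 2 fell adjusted over the list alone, the stem cell receptor LGR5 (-1.05, SE 0.165) and the transcription factor MECOM (-0.70, SE 0.147; list adjusted p = 0.20). None of the members named in these sentences passed over all features. With 1 array left out, as many or fewer members of the apoptosis, autophagy, Notch, YAP and ovarian lists passed. Such fits have fewer degrees of freedom and cannot show whether these changes rest on 1 array. After quantile normalization 4 autophagy genes rose, 1 apoptosis gene rose and 1 fell, and 1 ovarian gene fell. The Notch list passed without features below the 25th percentile (adjusted p = 0.037) or the median (0.0038, range over settings 0.0038 to 0.21).

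Adjusted over the list alone, 0 of 29 mesenchymal, 0 of 28 epithelial, 0 of 24 TGF-beta and 0 of 19 microRNA machinery genes passed, and the lists had adjusted p-values of 0.80, 0.65, 0.58 and 0.41. With the intensity trend 2 mesenchymal genes rose and 4 fell, 1 epithelial gene rose and 2 fell, 3 TGF-beta genes rose and 3 fell, and 1 microRNA machinery gene fell. Markers of other cell types were tested because a culture can hold foreign cells. Of 18 endothelial markers 1 fell adjusted over the list alone, CDH5, the adhesion molecule VE-cadherin. It went from 8.10 ± 0.0495 to 7.02 ± 0.0141 (SD, n = 2 per group, adjusted p = 0.10 over all features, list adjusted p = 0.77). Its values were 8.13 and 8.06 in the controls and 7.01 and 7.03 with the inhibitor. The endothelial list had a median level of 4.59 log2 units, well below CDH5. Whether CDH5 came from the carcinoma cells or from foreign cells was not tested. Of 14 fibroblast markers 2 fell adjusted over the list alone, PDGFRA (-0.58, SE 0.145) and PDPN (-0.56, SE 0.147), both at the edge of the threshold (list adjusted p = 0.80). The inhibitor mean of PDGFRA (3.805) lay within the dimmest 25% of features (up to 3.965), so its difference is uncertain. PDPN had a control mean of 10.2, against a median level of 3.96 for the fibroblast list. That fibroblast count was 0 with the robust prior, quantile normalization, equal array medians, cyclic loess, array weights and without any 1 of the 4 arrays. Of 18 leukocyte markers 0 passed (list adjusted p = 0.26). Over the 32 lists camera called 12, 7 up and 5 down, 10 of them the same way after quantile normalization. An estimated correlation called 0, with a lowest adjusted p of 0.35, and fry called 2, the histones and the NF-kappaB list. The estimate was -0.038 for NF-kappaB, -0.01 for NRF2 targets and 0.017 for histones, near or below the preset 0.01. Correlation between members thus does not by itself account for losing those calls, and that variant rests on 2 residual degrees of freedom. Estimates were higher in other lists, such as 0.12 for S phase, 0.16 for mitosis and 0.48 for ribosomal proteins. Camera compares a list with the other features and not with 0, and the median change of all features was -0.07. Its direction was up for the miR-204 targets, angiogenesis inhibitors, TGF-beta, endothelial and fibroblast lists with medians and means below 0, and for the hypoxia, interferon and autophagy lists with medians below 0 and means above.

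**Figure D3:**
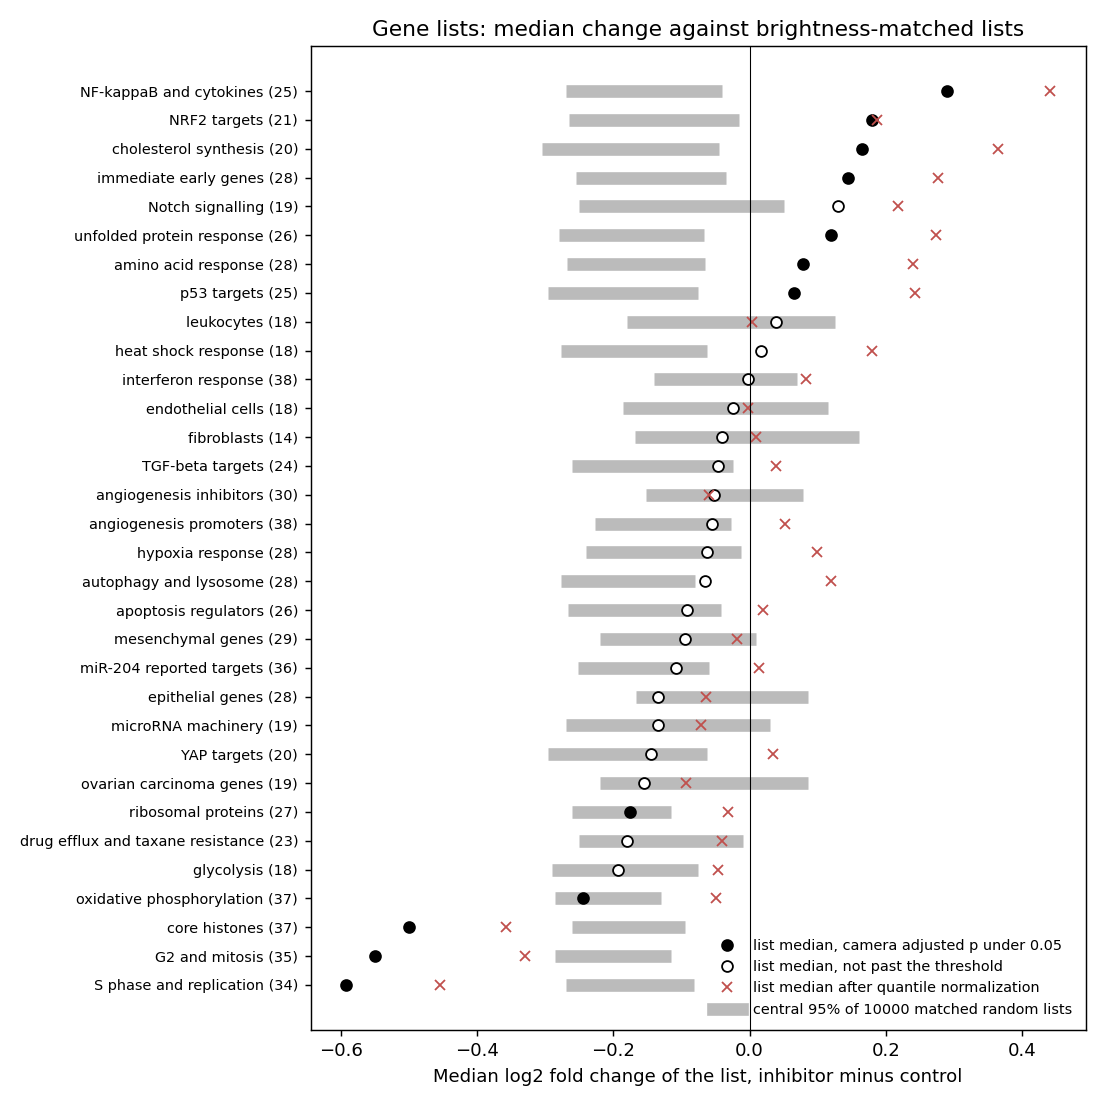
Median log2 fold change (inhibitor minus control, 2 arrays per group) of each of the 32 gene lists, with the number of measured genes in brackets; filled points passed camera, crosses are medians after quantile normalization, and grey bars span the central 95% of 10000 random lists matched on expression level. The S phase, mitosis and histone medians (-0.59, -0.55 and -0.50) lie below their bars, and the ribosomal and oxidative phosphorylation medians lie within theirs.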

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

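Cyclic loess, quantile normalization with the intensity trend, and array weights were chosen after the data were seen; the other settings were planned. The 11 features past the threshold in limma were higher under every setting that tested them, but their number moved. It was 1525 with the intensity trend in the prior (219 higher, 1306 lower), 38 without features below the 25th percentile (28 higher, 10 lower), 1011 without those below the median (144 higher, 867 lower), 559 with quantile normalization and the trend (304 higher, 255 lower) and 19 with array weights (18 higher, 1 lower). Quantile normalization gave 0 (0 higher, 0 lower; lowest adjusted p 0.058, 2932 features at an unadjusted p under 0.05). Leaving out any 1 array gave 0 features, with 924 to 5878 at an unadjusted p under 0.05. The ordinary test gave 0 after adjustment and 2702 before, and treat gave 1. The robust prior gave 11, equal array medians 10 and cyclic loess 8. The filters test fewer features, and the trend raised the prior degrees of freedom from 4.78 to 11.3; beyond that the cause was not tested.

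The replicate numbers shared by the groups did not pair the arrays: deviations from the group means of control array 1 and inhibitor array 1 correlated at 0.0058 across features. With the replicate block limma called 0 features (0 higher, 0 lower), with 3220 at an unadjusted p under 0.05 and a lowest adjusted p of 0.322, and 12 lists. The 108 features changed at least 2-fold at an unadjusted p under 0.05 became 51 without features below the median, and 110 to 314 with 1 array left out, 314 without inhibitor array 2. The THBS1 difference of 0.575 passed with the trend (adjusted p = 0.0038) and without features below the median (0.036), as did 0.752 with quantile normalization and trend (4.1e-04). It ranged from 0.485 to 0.665 with 1 array left out and up to 0.788 with cyclic loess, with adjusted p from 4.1e-04 to 0.83 over the settings.

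Camera called 9 to 17 lists over the settings, against 12, but 0 with an estimated correlation and 2 with fry. The ribosomal protein median of -0.175 was reversed to 0.033 by cyclic loess, and the cause was not tested. Where a list or named gene passed neither before nor under the setting, list directions changed in 31 of 251 comparisons and gene signs in 7 of 1426. The seed match test and all variants of it, including longer sites and an estimated correlation, were not run, because transcript sequences were not used here. Signal over background was not analysed here, so what dim features can show stays unknown.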

Other observations

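The tests of gene families, of genes outside the fixed lists, of the signal range for each of the 3 patterns below and of the interferon response were chosen after the results were seen; the tests of medians without single arrays were set before, and those of the calls without single arrays and the bounds of the medians after. Among the 108 features changed at least 2-fold at an unadjusted p under 0.05, the following genes lie outside the fixed lists, were chosen after their values were seen and did not pass over all features. TXNIP, a thioredoxin inhibitor that responds to glucose, differed by 1.80 log2 units (SE 0.198, n = 2 arrays per group, adjusted p = 0.072), and GDF15, a secreted stress cytokine, by 1.43 (SE 0.152, adjusted p = 0.068). SAA1, an acute phase protein, differed by 1.31 (SE 0.154, adjusted p = 0.08) and the collagenase MMP1 by 1.08 (SE 0.139, adjusted p = 0.10). On the lower side were the neuropeptide NMU (-1.37, SE 0.181, adjusted p = 0.10), the cell cycle factor E2F8 (-1.25, SE 0.252, adjusted p = 0.14), the meiotic recombination factor MND1 (-1.34, SE 0.242, adjusted p = 0.13) and the centriole kinase PLK4 (-1.08, SE 0.202, adjusted p = 0.14). Each of these kept its sign after quantile normalization and after cyclic loess.

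Families of genes that share a symbol prefix and hold at least 15 members were also tested with camera. Of 127 families 23 passed, and 0 passed also after quantile normalization. Of 47 mitochondrial ribosomal genes with the prefix MRPL 45 were lower (median log2 change -0.32, adjusted p = 2e-05, and 0.065 after quantile normalization), and the median ranked at 0.06% of brightness-matched random lists. Of 20 nucleoporin genes with the prefix NUP 19 were lower (median -0.38, adjusted p = 0.0021, and 0.065 after quantile normalization), at 0% of matched lists. Of 86 keratin-associated genes with the prefix KRTAP 58 were higher (median 0.10, adjusted p = 0.004, and 0.17 after quantile normalization), at 99.61% of matched lists.

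Bright features were lower in the inhibitor arrays, with a median log2 change of -0.20 in the brightest 25% against 0.07 in the dimmest. A narrower signal range of the inhibitor arrays and a real drop of abundant transcripts cannot be told apart: the oxidative phosphorylation, glycolysis and ribosomal medians lay within the central 95% of brightness-matched lists, the lowest at the percentile 16.84, as either would give, and control features without cell RNA were not used here. Without inhibitor array 1, the array with the narrowest range, the median change still fell from 0.025 in the dimmest 25% to -0.16 in the brightest 25%. This weaker trend rests on 1 inhibitor array. The brightest features lay at -0.09 relative to all features, between the bounds set beforehand, so that rule did not decide. The remaining trend shows that array 1 did not make all of it in these data. How much array 1 added stays open. A change in total RNA per cell, which the inhibitor could bring, was not tested.

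The S phase, mitosis and histone lists were lower beyond this trend, although camera with an estimated correlation did not call them (adjusted p = 0.44, adjusted p = 0.44 and adjusted p = 0.35). That variant had little power with 2 residual degrees of freedom. The signal range of the arrays does not account for them: 0 of 10000 brightness-matched lists, which do not carry the correlation between list members, had a median as low as that of any of the 3 (highest percentile 0), and after quantile normalization the medians were still -0.45, -0.33 and -0.36. Nor did 1 array decide, since the weakest of the 3 medians over the 4 left-out arrays lay at -0.395 relative to all features, and the highest camera adjusted p in these fits was 4.7e-08. Proliferation was not measured, and the loss of miR-204-5p was not checked, so no biological explanation was tested. A difference in cell density or harvest between the cultures was not tested either.

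The 7 lists of stress, cytokine, cholesterol and p53 genes were higher with camera's preset correlation, but none was called with an estimated correlation (adjusted p = 0.35 for NF-kappaB to adjusted p = 0.64 for the unfolded protein and amino acid responses). That variant had little power with 2 residual degrees of freedom. The estimates exceeded the preset 0.01 in some of the lists, up to 0.27 for the unfolded protein response. There the preset p-values may be too small. The signal range does not account for them, as all 7 medians ranked above those of all matched lists, which do not carry the correlation between members (lowest percentile 100), and the 7 medians after quantile normalization lay at 0.19 to 0.44. An interferon-type response to the oligonucleotides stays open by its rule, as neither outcome was met. The interferon median of -0.002 lay within the central 95% of matched lists, at percentile 71.66, so it showed no list-wide rise. Its 95% bootstrap interval had an upper end of 0.12, below the NF-kappaB median of 0.29. But its members went both ways, and camera called the list higher without features below the median level (adjusted p = 0.043). Without inhibitor array 2 the immediate early, NRF2, p53 and amino acid calls ended (highest adjusted p 0.14), with medians relative to all features of 0.135, 0.13, 0.145 and 0.102 against 0.215, 0.25, 0.135 and 0.148 with all arrays, but none moved beyond its bootstrap bounds, so whether 1 array decides these calls stays open. All 7 medians stayed above that of all features in every left-out fit, the lowest by 0.102. Bootstrap intervals lay above it in every such fit for only 3 lists, NF-kappaB, cholesterol synthesis and the unfolded protein response. These intervals resample list members and do not measure the spread between arrays. By the rule set beforehand, no single array decided the direction of the 7 medians. For the lists other than those 3, the interval reached the median of all features in some left-out fit. The direction of those lists therefore stays less certain. A stress response to the transfection or culture that differed between the groups and an effect of miR-204-5p loss were not told apart by any test here.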
